A study of Mus musculus with 18 samples.

How the data were processed

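Cells of lungs, spleens and implanted biomaterial scaffolds from female BALB/cJ mice were measured by Drop-seq, a droplet method in which each cell is caught with a barcoded bead so that every transcript carries a cell barcode and a unique molecular identifier (UMI). Tumour-bearing mice had received 2000000 4T1-tdTomato-luc2 cells, a labelled line of the 4T1 mouse mammary carcinoma, in a mammary fat pad 7, 14 or 21 days earlier, and healthy mice of the same days had received none. Each of the 3 tissues gave 1 library per status and day, 18 libraries in all. The labels do not say how many animals went into a library, so the p-values below measure the spread between libraries.

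The deposited values are raw UMI counts per gene and cell barcode, 1 table per library, made by the authors with mm10 as genome build and Seurat version 2 as named tool. Per the labels about 1000 bead and cell pairs (STAMPs) were amplified per library; the aligner, the gene annotation, the repair of bead barcodes and the calling of cells are not given in the sources used here. The tables hold 26397 barcodes, 39064142 UMIs and 22049 genes, and the lowest number of genes per barcode was 200 in each of the 18 tables. Library totals ranged from 292765 to 4530115 UMIs and the median per barcode from 383 to 1034.5 UMIs. Gene symbols were matched to the current reference table: of 423 genes in the fixed lists and markers, 411 matched by symbol and 8 by an older symbol. The files list Wfdc21 as 1100001G20Rik, Adgre1 as Emr1, Fcmr as Faim3 and Jchain as Igj, and these older symbols are kept below. Ccl19, Cxcl11, Ighd and tdTomato were not found among the symbols. Coordinates are those of GRCm38.

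The design, the gene lists, the markers, the rule for named genes and the first set of alternative settings were fixed before the data were examined. Cells with 200 or more genes and under 20 percent mitochondrial UMIs were kept, 24536 in all. Barcodes alike in their first 11 bases were not merged in the main run. Merging them would take out 120 (of 555, healthy spleen) to 289 barcodes (of 1701, tumour-bearing scaffold) per library at day 7. At days 14 and 21 it would take out at most 19 per library. Shares and intervals at day 7 may therefore count 1 cell more than once. Counts were scaled to 10000 per cell and log-transformed with scanpy 1.11.5. From 2000 variable genes 30 principal components and 15 nearest neighbours were taken, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 over all libraries together gave 28 clusters. Clusters were named from the fixed markers, with thresholds set after the clusters were seen: 3 markers at least 1.5 times higher than in other cells and a comparison with the 10 leading genes. Names carry the ending "-like" because they rest on RNA alone. In all, 7 clusters with 5838 cells were left without a name. No doublets were removed. Scrublet, as run by scanpy on each library alone, marked 0.249% of the 24536 kept cells. Whether it worked on these libraries at so low a share was not tested, so pairs of cells under 1 barcode may remain in the data.

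Counts were summed over the kept cells of each library and tested with the quasi-likelihood method of edgeR 4.0.16 (R 4.3.3), with TMM factors and the filter filterByExpr, which left 11158 genes. A single model held all 18 libraries, with a term for each tissue and day and a tumour term within each tissue, so that the day was a block; it left 6 residual degrees of freedom, and the biological coefficient of variation was 0.315. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. To describe this pairing, the tumour-bearing and the healthy library of a tissue and day were compared as deviations from their group means of log2 CPM. The correlation across genes ranged from 0.185 to 0.625 in the 9 pairs, where genes are not independent replicates. The highest correlation with another day ranged from -0.519 to 0.359, but deviations from a mean of 3 libraries lower it by construction. At day 21 shared barcodes can also raise the correlation within a pair. These values therefore cannot decide whether the block is needed. The same model was used for the difference between the tumour effects in lung and scaffold, for a linear change of the tumour effect with day, and for counts summed within each class that had 20 or more cells in a library. Numbers of cells per class were tested in edgeR with the number of kept cells as offset over 37 class and tissue pairs. Shares were also compared with a 2-sided exact permutation test of 3 against 3 libraries, whose smallest possible p is 0.1. Intervals of shares are exact binomial (Clopper-Pearson) 95 percent intervals and cover counting error only.

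Gene lists (30, including ribosomal protein and mitochondrial genes) were tested with camera from limma 3.58.1, with a small preset correlation between genes and with an estimated one, and with fry, adjusted over 84 list and tissue tests. With the preset correlation camera called 16 lists in lung, 16 in scaffold and 17 in spleen. It also called 6 to 15 per tissue when the same libraries were split otherwise, so its p alone is weak evidence of a tumour effect. The adipocyte and platelet lists had fewer than 5 measured members and have no such test. The p of fry tests whether the members of a list move, on balance, in 1 direction. It is printed below for every list that passed it (adjusted p under 0.05). Lists given below without a fry p did not pass it. At single days there was 1 library against 1, so list medians were set against 10000 random lists of matched expression and no p was computed.

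Named genes followed the rule fixed in advance: for each tissue the 8 largest rises and the 8 largest falls among called genes with 1 sign at all 3 days and a mean of 20 CPM (UMI counts scaled to library size) or more, filled up to 4 with values where fewer passed. It also took for each list the 3 members with the smallest p, for the other tests the 5 largest in each direction and for single days the 5 largest differences with 50 CPM or more. Mitochondrial, ribosomal, immunoglobulin V and predicted genes were skipped in the rankings of single genes.

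Alternatives fixed in advance were other scalings, other gene filters, DESeq2 1.42.0, every barcode in the tables or cells with 400 or more genes, other resolutions, Scrublet calls removed, each tissue clustered or fitted alone, no replicate block, haemoglobin genes left out, genes that lead another class left out, and each replicate (day) left out in turn. Added after the data were seen were 3 alternatives for barcodes found in several libraries of a day. In these, each such barcode was kept only in the library with at least 5 times the UMIs of the next (with barcodes alike in their first 11 bases merged), the same was done with day 21 left out, or the cluster made up of such barcodes was left out. Also added were the count of an unnamed cluster led by Irg1 as neutrophil-like and the shares of cells outside the neutrophil-like class. The tests were tested on simulated data with the means, depths and dispersions of these libraries. Of genes changed 4-fold, 60.6% were recovered in lung, 83.9% in scaffold and 50.7% in spleen, and 26.9% for a difference between lung and scaffold. For a change with day the shares at 4-fold were 31.3%, 49.2% and 26.9%. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.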

Results

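The series follows lungs, spleens and implanted biomaterial scaffolds, implants that host cells enter, of mice with and without a 4T1 mammary tumour. Droplet libraries were made 7, 14 and 21 days after tumour cells were injected, 9 from tumour-bearing and 9 from healthy mice, with 1 library per tissue, status and day. There are therefore 3 libraries per tissue and status, each of another day, and a difference at a single day has no test. Library totals lay between 292765 UMIs (healthy spleen, day 21) and 4530115 UMIs (tumour-bearing scaffold, day 7). The number of barcodes lay between 513 and 3415.

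Many cell barcodes of day 21 were found in more than 1 library. Of 7545 distinct barcodes of that day 1046 occurred in 2 or more libraries and 243 in all 6, against 279 of 5684 at day 7 and 103 of 8932 at day 14. When each shared barcode was given to the library that held at least 5 times the UMIs of the next, 80.1% of the UMIs of the healthy lung and 93.3% of those of the healthy spleen at day 21 fell to no library or to another one. In that spleen library 27 barcodes remained. These 2 libraries stood apart from all others, whose shares of UMIs did not exceed 14.3%. Counted as barcodes, the unit of the class shares below, 76% in that lung and 94.7% in that spleen library fell so. Among the other libraries this share of barcodes reached 30.4% at day 21 (tumour-bearing lung). It reached 28.5% at day 7 (healthy spleen) and 3.38% at day 14 (tumour-bearing spleen). The other libraries were thus not free of such barcodes, and the results were also computed without them.

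**Figure D1:**
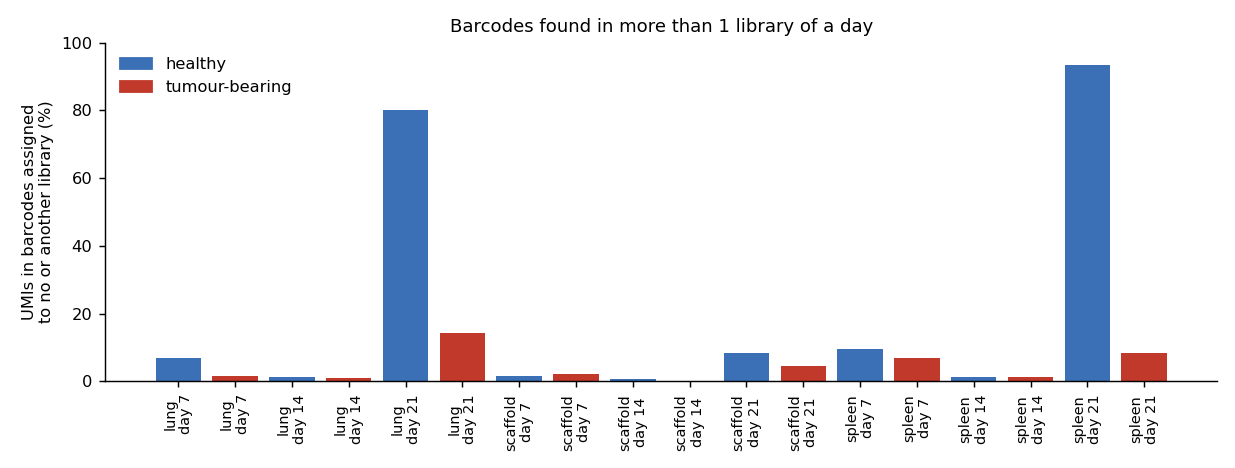
Percent of the UMIs of each of the 18 libraries (bars, by tissue and day; blue, healthy; red, tumour-bearing) that lie in barcodes assigned to no library or to another library of the same day. The healthy lung and healthy spleen of day 21 reach 80.1% and 93.3%, and the highest of the others is 14.3%.

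The first question was which cell classes made up each tissue. Neutrophil-like cells, the short-lived phagocytes named here by genes such as S100a8, Csf3r and Ly6g, rose in tumour-bearing mice in all 3 tissues. In lung their share was 4.61% ± 3.48 (SD, n = 3) in healthy and 53.5% ± 12.5 in tumour-bearing libraries, a log2 fold change of 3.87 ± 0.70 (SE). In scaffold it was 1.86% ± 1.44 against 20% ± 17.8 (log2 3.37 ± 0.685), and in spleen 1.02% ± 0.43 against 31.3% ± 18.4 (log2 4.74 ± 0.747). The share was higher at each of the 3 days in each tissue, with adjusted p = 6.69e-06, 5.36e-05 and 3.92e-07 in edgeR with Benjamini-Hochberg (BH) correction. Spleen also held more neutrophil progenitor-like cells, which carry the early granule genes Elane and Mpo (log2 2.29 ± 0.74, adjusted p = 0.0144 in edgeR, higher at 3 of 3 days). Its monocyte-like share was higher too (log2 1.87 ± 0.676, adjusted p = 0.0291 in edgeR, 3 of 3 days).

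In lung the share of alveolar macrophage-like cells, the resident phagocytes of the air spaces, fell by 2.37 ± 0.665 on the log2 scale (13.6% against 4.33%, adjusted p = 0.00561, lower at 3 of 3 days). The share of alveolar type 2-like cells, a cluster led by Scgb1a1 of club cells and the surfactant gene Sftpc and named airway epithelial-like when lung was clustered alone, fell by 2.35 ± 0.702 (adjusted p = 0.00927, lower at 3 of 3 days), and that of endothelial-like cells fell by 2.25 ± 0.813 (adjusted p = 0.0291, lower at 2 of 3 days). B cell-like cells made up 15.9% ± 12.5 of healthy and 6.44% ± 5.69 of tumour-bearing lung libraries, which did not pass the test (adjusted p = 0.0581 in edgeR). In scaffold plasmacytoid dendritic cell-like cells, a class known for making type I interferon, fell by 2.40 ± 0.776 (1.34% ± 0.236 against 0.257% ± 0.134, adjusted p = 0.0144 in edgeR, lower at 3 of 3 days). Of 37 class and tissue pairs, 9 were called. A share falls when another class grows, so shares were also taken of the cells outside the neutrophil-like class. There the lung values were -1.30 for alveolar macrophage-like, -1.34 for alveolar type 2-like and -1.04 for endothelial-like cells, and plasmacytoid dendritic cell-like cells in scaffold lay at -2.08. None of these 4 passed (adjusted p = 0.177, 0.203, 0.701 and 0.0626 in edgeR), while spleen monocyte-like (2.43) and neutrophil progenitor-like cells (2.95) passed. Without the replicate block 1 call was left, neutrophil-like cells in spleen, and the log2 values in lung and scaffold were 3.54 and 3.41 with adjusted p = 0.0504 in edgeR. The exact permutation test of 3 against 3 libraries gave 0.1, its smallest possible p, for the neutrophil-like share in each tissue, plasmacytoid dendritic cell-like cells in scaffold and monocyte-like cells in spleen. It gave 0.2 for alveolar macrophage-like and alveolar type 2-like cells in lung and neutrophil progenitor-like cells in spleen, and 0.4 for endothelial-like cells in lung. Without day 14 edgeR called 3 classes and without day 21 it called 4.

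**Figure D2:**
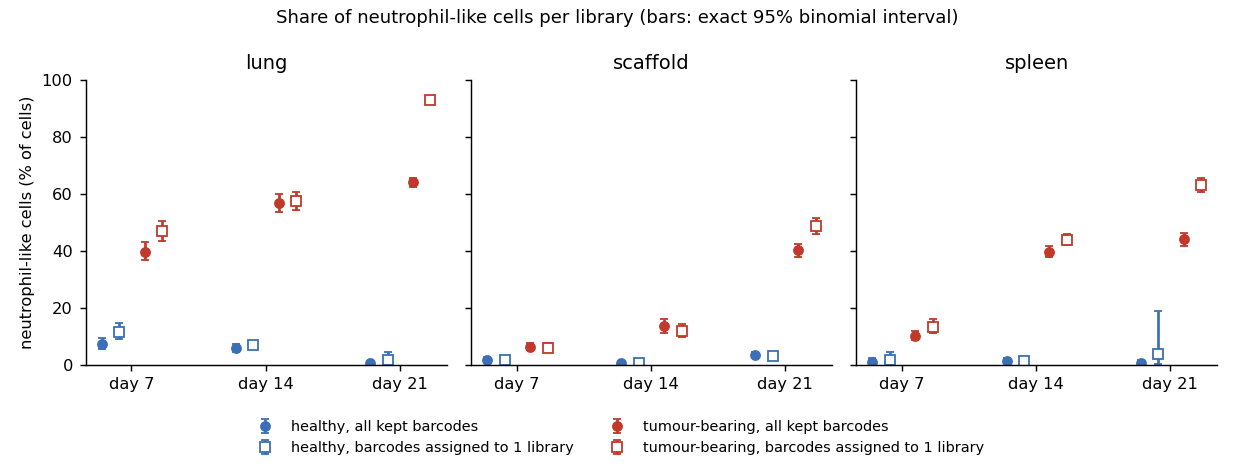
Neutrophil-like cells as percent of all cells in each library, by tissue and day, in healthy (blue) and tumour-bearing (red) mice; circles are all kept barcodes, squares only barcodes assigned to 1 library, and bars are exact 95 percent binomial intervals. In all kept barcodes the tumour-bearing libraries lie between 6.34% and 64%, the healthy ones between 0.541% and 7.3%.

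Clusters without a name held 5838 cells and stayed outside these classes. The largest, 2371 cells led by Ccl24, Clec4n and Fn1, made up 20.7% of healthy and 18.7% of tumour-bearing scaffold cells, 7.11% and 2.63% of lung cells and 10.5% and 4.26% of spleen cells (means of 3 libraries). When scaffold was clustered alone, clusters of 844 and 555 cells with Ccl24 and Clec4n among their 10 leading genes were named monocyte-like. The monocyte-like share in scaffold therefore depends on the clustering. A cluster of 2072 cells, 97.3% of them with shared barcodes, made up 16.5% of healthy and 5.64% of tumour-bearing lung cells, 9.01% and 0.619% of scaffold cells and 17% and 3.46% of spleen cells. Another, led by Irg1, Niacr1 and Csf1, made up 4.87% of healthy and 6.55% of tumour-bearing scaffold cells, and a cluster with the same leading pair was named neutrophil-like when scaffold was clustered alone. Counted as neutrophil-like, it took that share in scaffold to 6.73% ± 5.18 against 26.5% ± 13.8 (SD, n = 3), a log2 fold change of 2.28 ± 0.674 in place of 3.37 (adjusted p = 0.0101 in edgeR).

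Whole-library sums were then compared between tumour-bearing and healthy mice in each tissue. In lung the rises were led by genes of neutrophils. Prok2, a secreted chemoattractant of the prokineticin family, rose by log2 9.79 ± 0.656 (SE, 3 against 3 libraries), from 1 to 1620 UMIs over the group, a ratio of 852 with a counting interval from 153 to 33700. This and the ratios below are scaled to library size, with 95 percent intervals that cover counting error only, and a fitted fold from so few counts depends on the prior count. Stfa3 (log2 7.97 ± 0.695) and Stfa2 (8.03 ± 1.28), genes of the stefin A family of protease inhibitors, also rose; their sequences are close enough that counting could divide reads between them. Ly6g, the surface antigen by which mouse neutrophils are recognised, rose by 6.38 ± 0.793, Mapk13 by 6.06 ± 0.719 (3 against 656 UMIs, ratio 115, interval 39.2 to 559), Ceacam10 by 5.80 ± 0.578, Ifitm1, an interferon-induced membrane protein gene, by 5.47 ± 1.12, and Lrg1, a secreted glycoprotein of neutrophil granules, by 5.46 ± 0.581. All 8 were higher at 3 of 3 days, with adjusted p (edgeR, BH) from 6.44e-06 to 0.00996.

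Among the falls that the naming rule took in lung, Sftpc, surfactant protein C of type 2 cells, fell by 5.70 ± 1.37 on the log2 scale, Fabp1 fell by 4.19 ± 1.03, and Akap5 fell by 2.87 ± 0.751. Kitl, the ligand of the receptor Kit, fell by 2.76 ± 0.47, Retnla fell by 2.68 ± 0.764, and Emp2 fell by 2.57 ± 0.48. Each was lower at 3 of 3 days, with adjusted p (edgeR, BH) from 0.00388 to 0.0441. Eef1a2 and Uchl4 also fell by 4.07 ± 0.851 and by 2.70 ± 0.789, and both stood highest in the healthy library of day 21 (199 and 136 CPM). In GRCm38 Prok2 lies on chromosome 6 from 99711299 to 99726392, Ly6g on chromosome 15 from 75155240 to 75159126 and Sftpc on chromosome 14 from 70520949 to 70524081. In all 1012 genes were called in lung, 687 higher and 325 lower (708 and 217 with shared barcodes assigned to 1 library, 218 and 8 without day 21, and 310 and 14 with both). The rises were 67.9% of calls with TMM factors and 35.2% with library totals alone, a scaling under which the median of all genes lay at log2 -0.479 in place of -0.216. Without the replicate block 444 genes were called, without day 14 308, with cells of 400 or more genes 569, and with lung fitted alone 573.

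By list, 13 of 14 measured genes of mature neutrophils rose in lung (14 adjusted over the list alone; camera adjusted p = 9.96e-19, and adjusted p = 0.174 with an estimated correlation; fry adjusted p = 0.0217). They included S100a8 (log2 4.57 ± 0.678) and S100a9 (4.51 ± 0.651), which together form calprotectin. Of 18 genes associated with suppressive myeloid cells 12 rose (12 adjusted over the list alone; camera adjusted p = 1.12e-13, and adjusted p = 0.116 with an estimated correlation; fry adjusted p = 0.00339). Among them were Wfdc17 (5.19 ± 0.605), Nos2, the inducible nitric oxide synthase (6.03 ± 0.868; 1 against 314 UMIs, ratio 165, interval 29.4 to 6540), Arg2 (2.77 ± 0.346) and Il1f9, an interleukin 1 family cytokine (3.97 ± 0.502). Arg1, also on this list, had a log2 value of -0.15 ± 0.739 and did not pass. Among chemokines and cytokines 3 of 19 rose, Osm (3.48 ± 0.498), Il1b (3.32 ± 0.486) and Cxcl2, a neutrophil attractant (2.50 ± 0.44), and the list had no call (adjusted p = 0.291). Of 16 genes that cell dissociation is known to induce 6 rose (8 adjusted over the list alone; camera adjusted p = 6.51e-06, and adjusted p = 0.282 with an estimated correlation; fry adjusted p = 0.0452). They included the immediate early genes Fos (1.85 ± 0.343), Egr1 (1.97 ± 0.375) and Zfp36 (1.98 ± 0.376).

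Among lists of other cells the monocyte list moved up in lung, where 2 of 10 rose, F13a1 (1.93 ± 0.357) and Plac8 (1.51 ± 0.415), and 3 adjusted over the list alone (camera adjusted p = 0.0424, and adjusted p = 0.421 with an estimated correlation), and the plasma cell list had no call (camera adjusted p = 0.969). Several others moved down. Of 13 B cell genes 4 fell (7 adjusted over the list alone), among them Cd22 (-1.67 ± 0.387) and Ms4a1, which encodes CD20 (-1.62 ± 0.468); the camera adjusted p = 5.22e-04, and adjusted p = 0.503 with an estimated correlation. Of 9 endothelial genes 3 fell (3 adjusted over the list alone): Kdr, a receptor of vascular endothelial growth factor (-2.49 ± 0.524), Tmem100 (-2.23 ± 0.489) and Calcrl (-1.47 ± 0.34); camera adjusted p = 3.20e-04, and adjusted p = 0.398 with an estimated correlation. Of 9 alveolar epithelial genes 2 fell, Sftpc and Scgb1a1 of club cells (-2.35 ± 0.621), and 4 adjusted over the list alone (camera adjusted p = 0.0245, and adjusted p = 0.33 with an estimated correlation; fry adjusted p = 0.0336). Of 15 macrophage complement and lipid genes 3 fell (4 adjusted over the list alone), with Mrc1, the mannose receptor, at -1.83 ± 0.397 (camera adjusted p = 0.014, and adjusted p = 0.617 with an estimated correlation). Of 18 extracellular matrix genes 1 fell, Postn (-1.67 ± 0.481), and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.517 with an estimated correlation). None of 16 T cell genes was higher and none was called (camera adjusted p = 0.0116, and adjusted p = 0.629 with an estimated correlation; 0 adjusted over the list alone in edgeR). In the same libraries neutrophil-like cells made up 4.61% of healthy and 53.5% of tumour-bearing lung cells, and alveolar macrophage-like cells 13.6% and 4.33%.

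**Figure D3:**
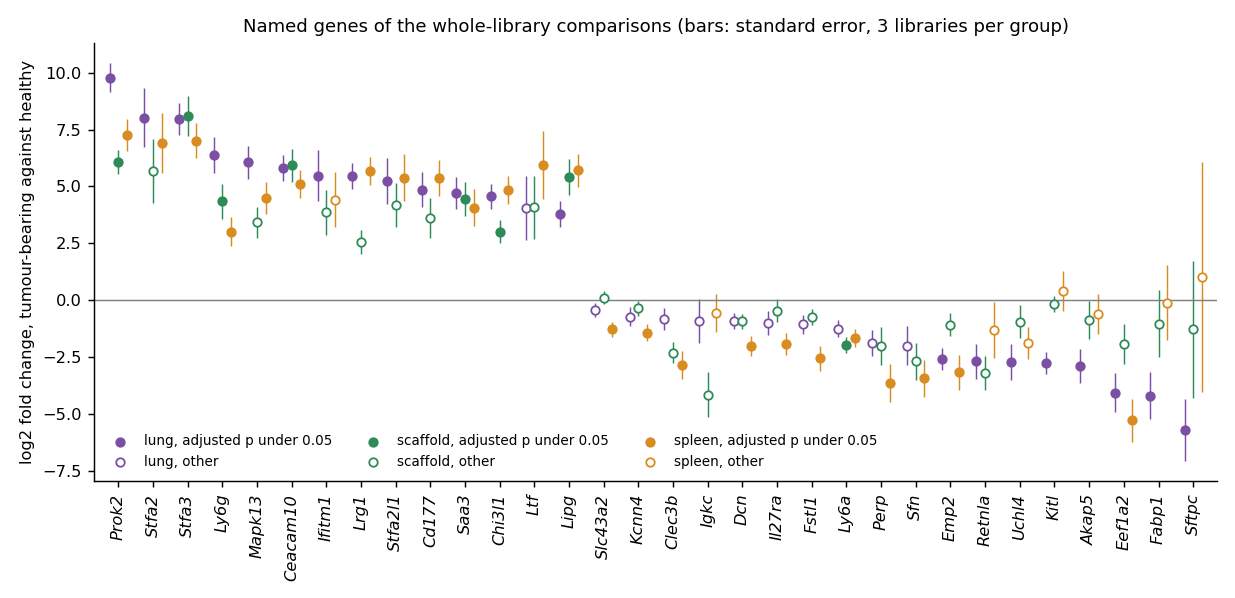
Log2 fold change, tumour-bearing against healthy, of the named genes in lung, scaffold and spleen; points are fitted values from 3 libraries per group, bars are standard errors and filled points have an adjusted p under 0.05. Prok2 reaches 9.79 in lung, 6.08 in scaffold and 7.26 in spleen, and Sftpc lies at -5.70 in lung.

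The same question in spleen gave early as well as late genes of the neutrophil lineage. All 11 genes of early granules rose (11 adjusted over the list alone; camera adjusted p = 1.22e-21, and adjusted p = 0.116 with an estimated correlation; fry adjusted p = 0.00445). Among them were Prtn3, a serine protease of azurophil granules (log2 3.92 ± 0.523), Ms4a3 (3.55 ± 0.427), Fcnb (3.77 ± 0.519) and Ltf, which encodes lactoferrin (5.96 ± 1.49). Of 14 genes of mature neutrophils 10 rose (13 adjusted over the list alone; camera adjusted p = 2.58e-17, and adjusted p = 0.179 with an estimated correlation; fry adjusted p = 0.044), with S100a9 at 4.49 ± 0.662. The largest rises of single genes were Prok2 (7.26 ± 0.687; 2 against 834 UMIs, ratio 138, interval 38.1 to 1140), Stfa3 (7.01 ± 0.77), Stfa2 (6.89 ± 1.32), Ltf and Lipg, an endothelial lipase gene (5.71 ± 0.734). Next came Lrg1 (5.68 ± 0.623), Stfa2l1 (5.39 ± 1.03) and Cd177, a neutrophil surface protein (5.37 ± 0.788). All were higher at 3 of 3 days, with adjusted p from 2.71e-04 to 0.0433 in edgeR.

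Of 18 genes associated with suppressive myeloid cells 8 rose in spleen (13 adjusted over the list alone; camera adjusted p = 6.12e-10, and adjusted p = 0.127 with an estimated correlation; fry adjusted p = 0.0104). Among them Wfdc17 lay at 4.39 ± 0.606 and Il1b at 2.96 ± 0.482, while Osm of the cytokine list rose by 4.24 ± 0.593. All 18 cell cycle genes were higher and 2 rose, Hmgb2 (2.47 ± 0.49) and Rrm2, a subunit of ribonucleotide reductase (3.02 ± 0.75), with 7 adjusted over the list alone (camera adjusted p = 8.34e-10, and adjusted p = 0.361 with an estimated correlation). Of 10 monocyte genes 2 rose, F13a1 (3.14 ± 0.408) and Plac8 (1.74 ± 0.432), and 4 adjusted over the list alone (camera adjusted p = 0.00572, and adjusted p = 0.329 with an estimated correlation). No member of the T cell list was higher; none fell over all genes tested in edgeR and 7 fell adjusted over the list alone (camera adjusted p = 2.26e-07, and adjusted p = 0.398 with an estimated correlation). In all 369 genes were called, 311 higher and 58 lower (84.3% higher, and 70.4% with library totals alone). Without day 21 148 were higher and 2 lower, and with barcodes assigned as well 337 and 10.

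Falls in spleen rested in part on the healthy library of day 21. Perp (-3.63 ± 0.832), Sfn (-3.43 ± 0.826), Fstl1 (-2.55 ± 0.549) and Dcn (-2.0 ± 0.436) stood at 328, 185, 171 and 109 CPM in that library and at no more than 13.6 CPM in the healthy libraries of days 7 and 14. With shared barcodes assigned to 1 library Perp lay at log2 2.82, the opposite sign (adjusted p = 0.651 in edgeR), Fstl1 at -3.58 and Dcn at -1.79, none of them past the threshold. Il27ra, a subunit of the interleukin 27 receptor (-1.93 ± 0.479), Kcnn4 (-1.43 ± 0.365) and Slc43a2 (-1.27 ± 0.325) fell as well and were lower at 3 of 3 days. Without the replicate block 72 genes were called in spleen, without day 7 659, without day 14 99 and without day 21 150; DESeq2 called 570 and edgeR on spleen alone 132.

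In scaffold 18 genes were called, 12 higher and 6 lower. Stfa3 rose by log2 8.10 ± 0.886, Prok2 by 6.08 ± 0.541, Lipg by 5.40 ± 0.787, Saa3, an acute-phase serum amyloid A gene with close paralogs, by 4.45 ± 0.753, and Chi3l1, a chitinase-like protein gene, by 3.02 ± 0.499, each higher at 3 of 3 days (adjusted p from 2.47e-04 to 0.0332 in edgeR). Nos2, with 0 UMIs in healthy libraries and 72 in tumour-bearing ones, was at least 22-fold higher (floor of 3 counts over the group, adjusted p = 0.0498 in edgeR), and Ly6g rose as well (4.35 ± 0.772, adjusted p = 0.0438). Ly6a, which encodes the antigen Sca-1, fell by 1.95 ± 0.356 (adjusted p = 0.0499 in edgeR, lower at 3 of 3 days). Clec3b (-2.31), Igkc, the kappa light chain constant gene (-4.15), and Retnla (-3.19) were lower at each day and did not pass. Saa3 lies in GRCm38 on chromosome 7 from 46711998 to 46715700.

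Of 14 genes of mature neutrophils 2 rose in scaffold, and 10 adjusted over the list alone (camera adjusted p = 3.83e-26, and adjusted p = 0.127 with an estimated correlation, fry adjusted p = 0.0814). No list passed fry in scaffold. None of the 20 genes of the type I interferon response was higher and none was called by edgeR, over all genes or over the list alone (camera adjusted p = 1.08e-11, and adjusted p = 0.329 with an estimated correlation; median log2 -0.724). None of the 10 MHC class II genes was higher or called (camera adjusted p = 1.28e-08, and adjusted p = 0.287 with an estimated correlation; 0 adjusted over the list alone in edgeR; median log2 -0.876). Of 19 genes of the interferon gamma response 2 were higher and none was called in edgeR (camera adjusted p = 3.87e-06, and adjusted p = 0.329 with an estimated correlation). Of 9 dendritic cell genes none was higher and 1 fell adjusted over the list alone (camera adjusted p = 6.76e-05, and adjusted p = 0.174 with an estimated correlation). Of 7 plasma cell genes none was higher and 3 fell adjusted over the list alone (camera adjusted p = 5.04e-06, and adjusted p = 0.274 with an estimated correlation). Without the replicate block edgeR called 0 genes in scaffold (233 at an unadjusted p under 0.05), and DESeq2 with the block called 43; the count was 33 without day 7, 6 without day 14, 2 without day 21, and 35 with shared barcodes assigned.

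Lung and scaffold were compared directly, since scaffolds of this kind are used as implanted stand-ins for a metastatic site. In edgeR no gene had a tumour effect that differed between them at adjusted p under 0.05 (1062 at an unadjusted p under 0.05), DESeq2 called 50, and edgeR called 149 when every gene with a count was tested. Across the 11158 genes the log2 fold changes of lung and scaffold had a Pearson r of 0.554 and a Spearman rho of 0.501, those of lung and spleen 0.587 and 0.485, and those of scaffold and spleen 0.482 and 0.273. Genes are not independent replicates, so no p is given. For lung and scaffold r was 0.0846 at day 7, 0.244 at day 14 and 0.646 at day 21, the day whose libraries shared many barcodes. Over all days r was 0.463 with shared barcodes assigned, and 0.236 with day 21 also left out. A rise of r with day therefore cannot be told from an effect of shared barcodes.

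Whether the tumour effect changed with day was tested as a linear trend. By edgeR no gene was called in lung, scaffold or spleen (696, 136 and 603 at an unadjusted p under 0.05), DESeq2 called 2, 0 and 0, and edgeR with every gene with a count called 34, 13 and 46. As values without a test, the median log2 difference of the mature neutrophil list in lung was 2.96 at day 7, 4.34 at day 14 and 5.62 at day 21, and in scaffold 0.946, 2.94 and 3.53. The early granule list stood at 3.22, 4.44 and 3.72 in spleen. The type I interferon list stood at 0.796, 0.356 and -0.698 in lung and at -0.591, 0.109 and -1.70 in scaffold, where day 14 went the other way. In lung its day 7 value lay at percentile 100, rounded, of 10000 random lists. Such lists ignore that members of a list move together, and the B cell and ribosomal protein lists lay at percentile 0 that day. Over all days the type I interferon list was not called in lung (camera adjusted p = 0.111). The interferon gamma list in scaffold stood at -0.419, 0.18 and -0.773. At day 21 in lung Il1r2, a decoy receptor of interleukin 1, differed by log2 8.77 (1 against 4048 UMIs, ratio 674, interval 121 to 26600) and Cxcr2, a chemokine receptor of neutrophils, by 8.17. Both were among the 5 largest differences upward of that day, and the largest downward was Sftpc (-9.22, with 428 against 1 UMIs, ratio 2570, interval 459 to 102000). In the healthy libraries of day 21, 80.1% of UMIs in lung and 93.3% in spleen lay in barcodes assigned to no library or to another one. The values of that day in these 2 tissues carry this limit, which the intervals do not cover. In scaffold the 5 largest differences upward of day 7 were mast cell protease genes. Tpsab1, Mcpt4 and Tpsb2 had 0 UMIs in the healthy library and were at least 167-fold, 100-fold and 95.4-fold higher (floor of 3 counts per library). Cpa3 (6.71) and Cma1 (6.38) had 1 UMI each there (ratios 374, interval 66.9 to 14800, and 297, interval 53 to 11700). The largest downward were the immunoglobulin genes Igha (-7.80, the largest in size of that day), Igj (-4.74) and Igkc (-4.03).

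**Figure D4:**
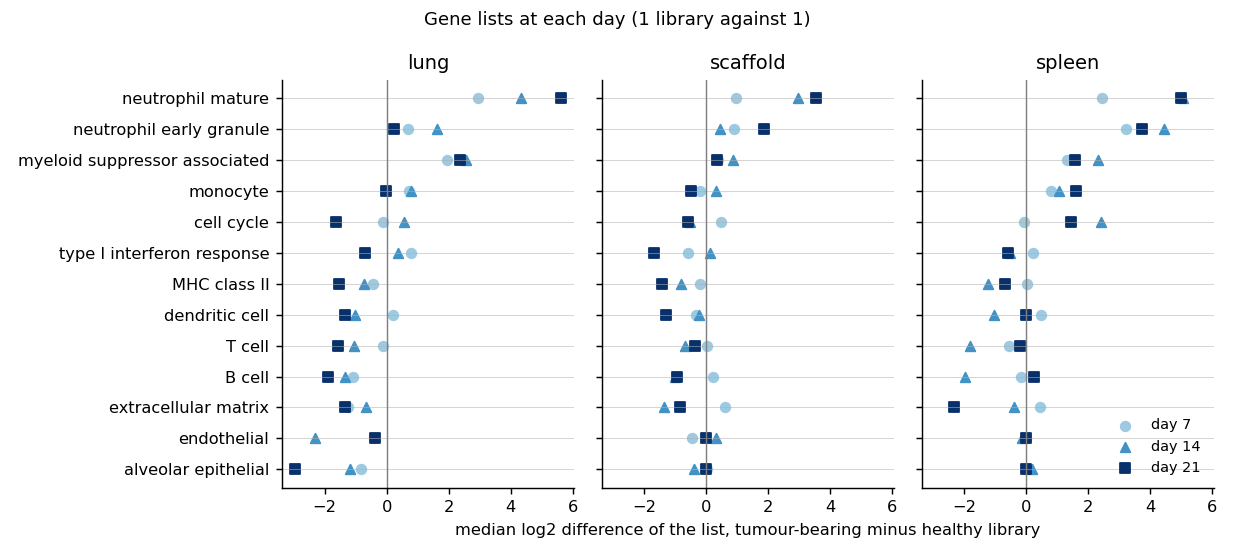
Median log2 difference between the tumour-bearing and the healthy library for the members of 13 gene lists, by tissue, with 1 symbol per day (1 library against 1, no test). The mature neutrophil list in lung lies at 2.96, 4.34 and 5.62 at days 7, 14 and 21. In healthy lung and spleen of day 21 most UMIs lie in barcodes assigned to no library or to another one.

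Within cell classes the question was which genes changed in cells of 1 kind. In monocyte-like cells of lung 12 of 1408 genes were called. Saa3 and Lcn2, the iron-scavenging lipocalin 2, had 0 UMIs in these cells of healthy lung and were at least 42.2-fold and 27.6-fold higher in tumour-bearing lung (floor of 3 counts over the group). S100a9 rose by log2 5.08 ± 0.813, S100a8 by 4.88 ± 0.766 and Lrg1 by 4.83 ± 1.06 (1 against 118 UMIs, ratio 38.2, interval 6.72 to 1520). Lpl, lipoprotein lipase, fell by 3.08 ± 0.538 (these 6 genes: adjusted p from 4.75e-05 to 0.0206 in edgeR, the same sign at 3 of 3 days). In monocyte-like cells of scaffold Saa3 alone was called (0 against 352 UMIs, at least 73.8-fold higher over the group, adjusted p = 1.06e-05 in edgeR). Dendritic cell-like cells had higher S100a8 and S100a9 in lung (3.88 ± 0.593 and 3.45 ± 0.552) and in scaffold (2.63 ± 0.446 and 2.54 ± 0.383), with Saa3 also higher in scaffold (5.45 ± 1.08; 1 against 35 UMIs, ratio 51.5, interval 8.65 to 2090); 2 genes were called in lung and 3 in scaffold. In macrophage-like cells of scaffold 1 gene of 8154 was called, Stfa2l1 (3.30 ± 0.465, adjusted p = 0.0442 in edgeR). In the same cells none of 20 type I interferon genes was higher (median log2 -0.806), and 11 fell adjusted over the list alone, though 0 over all genes. None of 14 interferon gamma genes was higher (5 fell adjusted over the list alone; median -0.515), and none of 8 MHC class II genes (7; median -0.896). No member of these 3 lists was called over all genes in edgeR, and no list test was run within classes. The macrophage-like class also holds a cluster of 192 cells led by the type I interferon genes Ifit2, Rsad2 and Ifit3. A change in the share of that cluster within the class cannot be told from a change within cells.

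Free RNA bears on these values, since S100a8 and S100a9 are among the most abundant transcripts of neutrophil-like cells. At day 14 in tumour-bearing lung S100a8 stood at 6750 CPM in monocyte-like cells and at 9440 CPM in the higher of T cell-like and B cell-like cells, classes that should lack it. At day 21, in barcodes assigned to that library, it stood at 14100 CPM in 48 monocyte-like, 10600 CPM in 15 B cell-like, 4180 CPM in 13 T cell-like and 1280 CPM in 18 alveolar macrophage-like cells. Saa3 at day 14 stood at 687 CPM in monocyte-like and 162 CPM in B cell-like cells. In dendritic cell-like cells of tumour-bearing lung S100a8 stood at 731 CPM at day 7 and 3950 CPM at day 14. T cell-like cells there held 3690 and 9440 CPM, so its rise in dendritic cell-like cells of lung cannot be told from free RNA. In tumour-bearing scaffold dendritic cell-like and NK cell-like cells held 729 and 239 CPM at day 7, but 183 and 4930 CPM at day 21. Of the 19 calls within classes 4 were left without the replicate block and 4 when genes that lead another class of the tissue were left out. Those last 4 were all rises in monocyte-like cells of lung. No call in dendritic cell-like cells or in scaffold was left there, nor the fall of Lpl. Leaving out day 7 gave 42 calls and leaving out day 14 gave 41. With shared barcodes assigned, edgeR called 53 genes in monocyte-like cells of lung and 24 in those of scaffold. It called 0 in macrophage-like cells of scaffold (209 at an unadjusted p under 0.05), so that Stfa2l1 was no longer called, and dendritic cell-like cells were not tested. The cells were clustered anew there, and a cluster of 1652 cells led by Ccl24, Clec4n and Cx3cr1 was named monocyte-like. In the main run a cluster led by Ccl24 and Clec4n had no name. In monocyte-like cells 5442 genes were tested in place of 1408, so the class is not the same one.

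**Figure D5:**
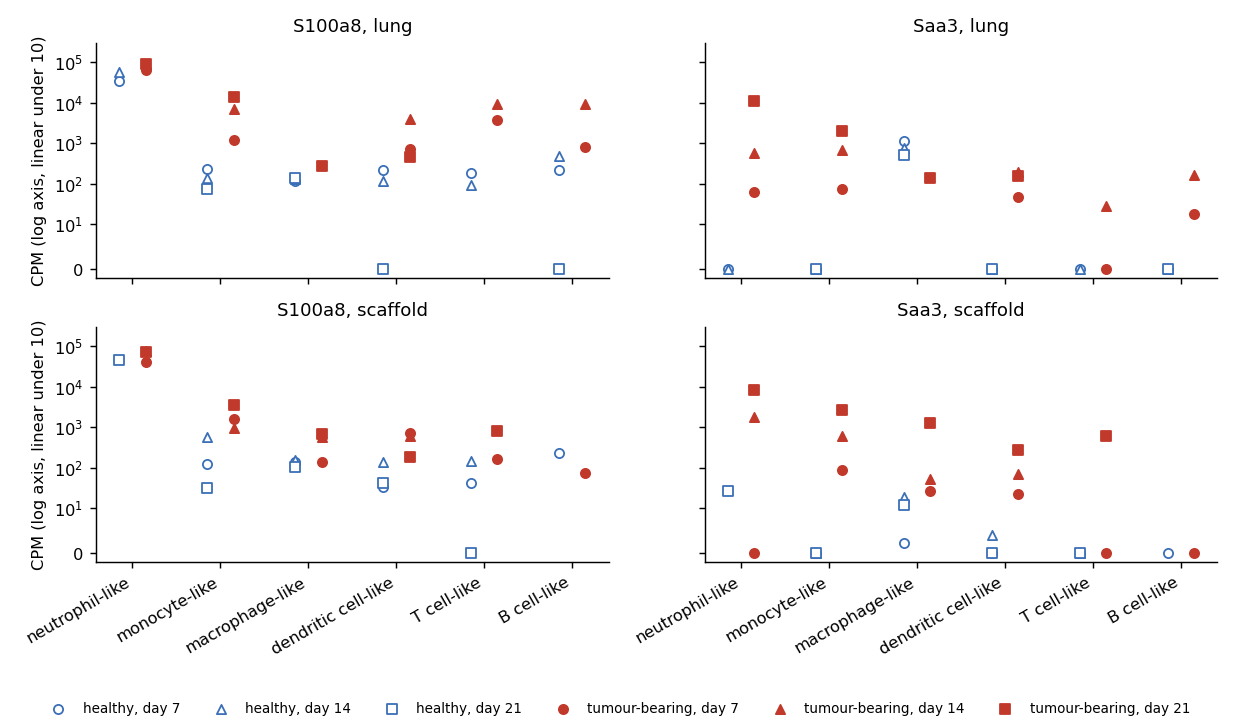
S100a8 and Saa3 in CPM (log axis, linear under 10) in 6 cell classes of lung and scaffold, by day, in healthy (open) and tumour-bearing (filled) libraries; each point is 1 library, and at day 21 most dendritic cell-like and macrophage-like barcodes of lung are shared with other libraries. In tumour-bearing lung at day 14 monocyte-like cells lie at 687 CPM for Saa3 and 6750 CPM for S100a8.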

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

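The tests of the neutrophil-like share and of the keratin genes, the test of S100a8 at day 21, and both Saa3 tests that go beyond the quotient over all 6 libraries were chosen after the results they bear on were seen. The test of a difference between tissues in cell shares was applied to all 34 class and tissue pairings.

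The share of the class named alveolar type 2-like stood out because tumour-bearing and healthy mice differed in opposite directions in lung and scaffold. The interaction term gave a difference of log2 -3.54 ± 1.01 (adjusted p = 0.0243 in edgeR over all 34 pairings), from a fall in lung (3.56% to 0.913%, log2 -2.35 ± 0.702) and a scaffold value that did not pass the test (0.867% and 1.91%, log2 1.19 ± 0.721, higher at 2 of 3 days, and 0.19 without day 21). Among the cells outside the neutrophil-like class the difference was -2.83 ± 0.939 and did not pass (adjusted p = 0.106 in edgeR), so it rests in part on the neutrophil-like share. Whether like cells are compared is open. Sftpc differed, at 0 UMIs among 75076 in the 117 scaffold cells and 709 among 128618 (5510 CPM) in the 131 lung cells. Scgb1a1 stood at 29900 and 38200 CPM and Ttn at 813 and 676 CPM. Scgb1a1 also stood at 268000 CPM in the 12 spleen cells of this class, which held 0 Sftpc UMIs, so its level does not tell lung cells from others here. With each tissue clustered alone 86.3% of the lung cells fell in a cluster named airway epithelial-like and 69.2% of the scaffold cells in one without a name, led by Gm10800, Trim44 and Zfc3h1.

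S100a8, S100a9 and Saa3 were higher in monocyte-like cells of tumour-bearing lung, and Saa3 in those of scaffold. Against RNA of neutrophil-like cells, free or in doublets, as the source of Saa3 stands its ratio to S100a8, at least 6.65 times that of neutrophil-like cells of the same library in all but the lung at day 21, where the quotient was 1.23 and the 2 sources cannot be told apart. For S100a8 the values that neutrophil RNA needs are there in lung at days 7 and 14, where monocyte-like cells held at most 0.715 times the level of the higher of T cell-like and B cell-like cells. At day 21 free RNA and a change in the cells cannot be told apart for S100a8: in barcodes assigned to that library monocyte-like cells held 1.33 times the level of 15 B cell-like cells, but 11.0 times that of 18 alveolar macrophage-like cells, and doublets stay open too. Free RNA of any source cannot be told apart for Saa3, which in the 3 libraries with Saa3 UMIs in a lymphocyte class stood at least 4.25 times above it, in lung at day 7 with 10 against 2 UMIs (lower limit 0.909), and a change within monocyte-like cells remains a candidate explanation.

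The neutrophil-like share was higher in tumour-bearing mice in lung, scaffold and spleen. Barcodes found in several libraries of a day are argued against as the whole cause, since the smallest of the 3 log2 values was 3.42 with each barcode assigned to 1 library (adjusted p = 0.00499 in edgeR). With 400 or more genes per cell the smallest of the log2 values was 4.24 (adjusted p = 0.0252 in edgeR), so the difference held under a stricter cut. A stricter cut cannot show what a lower one would give, so the part of the minimum of genes per cell stays open. In healthy lung neutrophil-like cells held 787 UMIs per cell at day 7 and 579 at day 14. In tumour-bearing lung they held 976 and 1220. With the unnamed cluster led by Irg1 counted as neutrophil-like the scaffold value was 2.28 (adjusted p = 0.0101 in edgeR), so its size there depends on that cluster. How cells were called in each library, how evenly neutrophils survived dissociation and the tumour itself stay open and were not tested.

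Keratin genes were called lower 18 times, 6 in lung, 1 in scaffold and 11 in spleen, over 11 genes, some with paralogs close enough to share reads. The values that shared barcodes of day 21 need are there: of the keratin UMIs of the healthy libraries of that day, 99.6% in lung, 99.1% in scaffold and 99.8% in spleen lay in barcodes assigned to no library or to another one, against 81.4%, 8.6% and 93.3% of all UMIs of the kept cells, and the 12 libraries of days 7 and 14 held 21 keratin UMIs. With barcodes assigned, 14 of the 18 fell below the count filter and none of the 4 tested was called. All 4 errors grew, and the fold of Krt14 was also smaller in lung and scaffold: Krt14 in spleen went from log2 -3.52 ± 0.583 to -6.51 ± 1.88, in scaffold from -4.10 ± 0.603 to -3.67 ± 1.5 and in lung from -2.42 ± 0.538 to -0.66 ± 1.13, and Krt17 in spleen from -3.43 ± 0.636 to -4.29 ± 1.8. RNA or cells carried between the libraries of day 21 is thus a candidate explanation of these falls, and where the keratin RNA came from was not tested.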

How the results depend on the processing

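The 3 alternatives for barcodes found in several libraries, the one that counts the cluster led by Irg1 as neutrophil-like, and the shares of cells outside the neutrophil-like class were chosen after the data were seen. Across all alternatives 1315 values of log2 fold changes kept their sign and their side of the threshold, 411 kept their sign and lost the call, and 2 reversed: Perp in spleen, 2.82 with shared barcodes assigned and 2.84 with day 21 also left out, where few counts remained. Of the values for gene lists 276 kept both, 113 lost the call and 2 reversed, the macrophage complement and lipid list in lung (adjusted p = 0.632 with barcodes assigned and day 21 left out) and the keratin list in lung (0.992 without the replicate block); neither was called there. The cause of the changes below was not tested, except that leaving out a day, an assigned barcode or a tissue leaves fewer libraries or counts, and that a test of every gene with a count takes in more genes. On simulated data with the depths and spread of these libraries 6.15% of 2-fold changes were recovered in lung, 9.68% in scaffold, 8.96% in spleen and 0% for the difference between lung and scaffold, against 86.2%, 87.9%, 86.4% and 67.7% of 8-fold changes; depth was not varied on its own, so its part in this was not told from that of the spread or the number of libraries. The alternative without erythroid-like clusters was not run, since no cluster had that name, and neither was the change with day without day 21 and with barcodes assigned, which leaves no residual degrees of freedom. Leaving out 1 day of 1 tissue takes the spread of the change with day from the other 2 tissues, as if the lone libraries varied like those.

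Genes called numbered 1012 in lung, 18 in scaffold and 369 in spleen. With every gene with a count tested they were 1613, 191 and 909. Without the replicate block they were 444, 0 (233 at an unadjusted p under 0.05) and 72, and without 1 day 226 to 1045, 2 to 33 and 99 to 659. Tissues fitted alone gave 573 in lung and 132 in spleen. Cells with 400 or more genes gave 569 in lung and 9 in scaffold, and DESeq2 called 43 in scaffold and 570 in spleen. With genes of 20 CPM or more scaffold had 6. With barcodes assigned scaffold had 35, and with day 21 also left out lung had 324 and scaffold 8. The difference between lung and scaffold, 0 in edgeR, went to 149 with every gene with a count, 50 with DESeq2, 1 with barcodes assigned, 7 with day 21 also left out and 0 to 1 without 1 day. Changes with day, 0 in edgeR, were 34 in lung, 13 in scaffold and 46 in spleen with every gene with a count, 2 in lung with DESeq2, 4 in lung with barcodes assigned and 1 in scaffold with 400 or more genes per cell.

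The 9 cell classes called were 1 without the block, 5 with barcodes assigned and day 21 left out, 2 as shares of the cells outside the neutrophil-like class, and 3 to 10 without 1 day. Outside that class all 3 falls in lung and the fall in scaffold lost their call. Neutrophil-like shares kept their call in lung, scaffold and spleen in all alternatives but 2: without the block, lung was 3.54 and scaffold 3.41, and the exact permutation p was 0.1 in each tissue. With lung clustered alone, a cluster of 844 cells led by Sycp2 and Irg1 had no name. Another of 1020 cells, led by Saa3 like a neutrophil-like cluster of the main run, had none either. Of genes called within classes, 19 over the 5 class and tissue pairs with 20 cells in each library, 1 was left with 50 or more cells per library and 4 without the block or without genes that lead another class; the count was 73 without Scrublet calls, 77 with barcodes assigned, 34 with day 21 also left out and 20 to 42 without 1 day. These counts cover those 5 pairs where they could still be tested. With day 21 left out 13 pairs could be tested and held 155 calls, and with barcodes assigned as well 10 pairs held 173. With Scrublet calls removed or barcodes assigned the cells were clustered anew, and a cluster led by Ccl24 and Clec4n, unnamed in the main run, was named monocyte-like. There 4800 and 5442 genes were tested in monocyte-like cells in place of 1408, so those counts and the 19 do not rest on the same class. List calls, 49, were 0 with an estimated correlation, 31 without the block and 30 to 50 without 1 day. The correlation r of lung and scaffold was 0.0846 at day 7, 0.244 at day 14 and 0.236 with barcodes assigned and day 21 left out. For lung and spleen it was 0.296 and 0.413 at days 7 and 14, and for scaffold and spleen 0.134, 0.0789 and, with barcodes assigned and day 21 left out, 0.208. Of 104 calls of named genes 90 were made by DESeq2, 97 with DESeq2 size factors, 25 without the block, 82 with barcodes assigned, and 90, 50 and 42 without day 7, 14 and 21.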

Other observations

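The values of the neutrophil-like clusters below were picked after they were seen, whereas the tests by splits of the libraries were set earlier. In lung further members of the gene lists rose. Lcn2 rose by log2 5.26 ± 0.845 (SE, 3 against 3 libraries), Ngp, also of the early granule list, by 4.20 ± 0.848, the 2 of its 11 genes called; over the list alone 4 rose and 1 fell (camera adjusted p = 0.0042, and adjusted p = 0.421 with an estimated correlation). Il4ra, the receptor chain for interleukins 4 and 13, rose by 2.38 ± 0.57. Entpd1, which encodes the ectonucleotidase CD39, rose by 2.09 ± 0.312 (adjusted p = 0.00197 in edgeR). Neither interferon list was called in lung: 1 of 20 type I genes rose, Oasl1 (1.88 ± 0.509; camera adjusted p = 0.111), and 1 of 19 interferon gamma genes, Irf1 (1.59 ± 0.332; camera adjusted p = 0.109). Gapdh was the 1 gene of the glycolysis and hypoxia list called over all genes in lung (1.82 ± 0.459); 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00432, and adjusted p = 0.503 with an estimated correlation). None of the 10 MHC class II genes was higher in lung or called by edgeR (camera adjusted p = 0.00639, and adjusted p = 0.517 with an estimated correlation).

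In spleen Hbb-bt, a beta globin gene, rose by 3.19 ± 0.768, the erythroid list having a camera adjusted p = 0.0155 and an adjusted p = 0.508 with an estimated correlation. The median log2 difference of that list was 2.20, 3.66 and -1.40 at days 7, 14 and 21, so the last day went the other way (values without a test). Hspa1a, a heat shock gene that dissociation induces, rose by 3.47 ± 0.693 and Cst7, a cystatin gene, by 1.76 ± 0.401, while Emr1, which encodes the macrophage antigen F4/80, fell by 1.74 ± 0.398. In scaffold all 16 genes of the dissociation list were higher (camera adjusted p = 7.61e-05, and adjusted p = 0.287 with an estimated correlation). Neutrophil-like cells fell into several clusters, one led by Il1b, Csf3r and Cxcr2, one by Saa3, Il1r2 and Mmp8, of whose cells 65.7% came from tumour-bearing lung at day 21, one by stefin genes and Retnlg, and a pair by the granule genes Ltf, Camp and Ngp. Saa3 in neutrophil-like cells of tumour-bearing lung stood at 60.7, 563 and 10800 CPM at days 7, 14 and 21, values of 1 library each without a test.

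Among genes of other cells, 1 of 3 measured adipocyte genes fell in lung, Lpl (-1.65 ± 0.445), with 2 adjusted over the list alone, and none was called in scaffold or spleen; neither of the 2 measured platelet genes was called. Of 104 ribosomal protein genes 4 fell in lung, among them Rpl10l (-3.89) and Rpl39l (-3.28), which have close paralogs (camera adjusted p = 2.17e-07, and adjusted p = 0.503 with an estimated correlation). In scaffold 1 fell, Rpl10l (-6.05; 139 against 1 UMIs, ratio 151, interval 26.7 to 6020; camera adjusted p = 0.0314, and adjusted p = 0.808 with an estimated correlation), and in spleen 3 fell (camera adjusted p = 0.0277, and adjusted p = 0.791 with an estimated correlation). Of 19 mitochondrial genes mt-Tm fell in lung (-1.62; camera adjusted p = 0.0294, and adjusted p = 0.535 with an estimated correlation), and none was called in scaffold (camera adjusted p = 0.688) or spleen (camera adjusted p = 0.0104, and adjusted p = 0.503 with an estimated correlation).

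The 3 against 3 libraries of a tissue make 10 splits, too few for a share under 0.05. The real split parts all 3 pairs of libraries of a tissue and day, as do 3 of the others; the other 6 part 1 pair each. Only the real split reached 1012 genes in lung, 18 in scaffold and 369 in spleen, the highest other being 0 in each tissue (1 of 10 splits as large). In the other splits the tumour effect of some days adds to the spread between libraries, which can lower their counts. The 0 of those splits is therefore no measure of what chance would give. The real split called 16 lists in lung and scaffold and 17 in spleen. The other splits called 11 to 14 in lung, 6 to 14 in scaffold and 7 to 15 in spleen. The count of lists thus hardly tells the real split from the others, and a small camera p with the preset correlation is weak evidence here. In lung and scaffold the highest others parted all 3 pairs. In spleen 15 was reached by a split that parts all 3 pairs and also by splits that part 1 pair. For classes the counts were 4 in lung (highest other 2, and 0 among the splits that part all 3 pairs), 2 in scaffold (0) and 3 in spleen (0). For changes with day the real count of 0 in edgeR was met by all 10 splits, and the highest others were 112 genes in lung, 0 in scaffold and 65 in spleen. The split with 112 swaps the labels of day 7, which by itself turns a constant tumour effect into a change with day, and the one with 65 parts 1 pair only, so the tumour effect is part of the structure of the samples that these counts point to. For the difference between lung and scaffold, tested on 10 splits of the 6 pairs, the real count was 0 and the highest other 1, so all 10 splits were as large. Within monocyte-like cells of lung 12 genes stood against 6, and within dendritic cell-like cells of scaffold 3 stood against 1. As large were 4 of 10 splits within dendritic cell-like cells of lung (2 against 11; 3 with all 3 pairs parted) and within monocyte-like cells of scaffold (1 against 11; 6). Within macrophage-like cells of scaffold 6 of 10 were (1 against 9; 6). Splits that call several times the real count point to a structure of the samples, and the tumour effect of single days is part of it.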
